A study of Sulfolobus acidocaldarius with 3 samples.

How the data were processed

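RNA of Sulfolobus acidocaldarius MW001 was sequenced in 3 libraries, 1 each from planktonic cells, biofilm cells and RNase R-treated small RNA. Per the labels' protocols, cells were taken in logarithmic phase, total RNA was extracted with TRIzol for the planktonic and biofilm libraries, small RNA was enriched with a mirVana kit before RNase R for the third, and libraries were made with a NEBNext small RNA kit for Illumina sequencing. The labels disagree on the HiSeq model. The aligner, counter and their settings are not given in the sources used here.

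The file analysed here was deposited as an annotated genome in GenBank format, and the values taken from it are feature locations, 1-based positions on the chromosome of strain DSM 639. Per the file headers, genes were annotated with the NCBI Prokaryotic Genome Annotation Pipeline, revision 3.0, and per the deposited qualifiers tRNA genes were found with tRNAscan-SE 1.23. It was searched for read counts, expression values and any qualifier naming a library, and holds none, so the number of columns of samples used was 0. Library depth is therefore unknown here and no interval or floor for reads is given. The comparison of biofilm with planktonic cells, with its planned ratios and counting intervals, and the shares within the RNase R library were not run. With 1 library per group they would have had no test. What was run is the part of the plan set for an annotation file. Its values describe 1 genome sequence, and its features are not replicates of samples.

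Features were parsed with Python 3.11.15, and all 2224 intact coding sequences, translated with biopython 1.88, gave the deposited protein. Statistics used numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9. RNA genes were placed as antisense, sense or between coding sequences by an overlap of at least 1 nt. Shares were compared with 10000 random placements of the same lengths on random strands (seed 7), with a two-sided empirical p and Benjamini-Hochberg adjustment over 3 placement classes. GC content of each class was compared with the same number of placements, adjusted over 3 RNA classes, and separately over the repeat classes that were added after the data were examined. The smallest p that the placements can give is 0.0002. Both tests were tested on simulated data. With RNA genes at random positions, 2% of 200 placement sets and 6% of 200 GC sets passed 0.05, and 100% of 200 sets passed both when 70 percent of the tRNA genes were placed between coding genes and, for GC, when 50 percent were placed in GC-rich windows.

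Coding sequences that share sequence were those with a 50-nt window found at any other place on either strand. CRISPR repeats were located by the annotated repeat unit with up to 4 mismatches, and spacers were compared with the chromosome outside the arrays by exact match on both strands. The intervals on shares of genes are 95% Wilson intervals. The RefSeq gene table given with the series, assembly ASM1228v1, has the same chromosome version, so its coordinates were compared directly. Of the genes analysed, 2246 shared a locus tag with it.

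The 13 gene lists were fixed before the data were examined and were matched by product wording or locus tag. They were archaellum and its regulators (12 coding genes), pili (10), biofilm regulators (3), S-layer and glycosylation (17), terminal oxidases (15), translation (80), RNA-guided modification (6), RNA degradation (9), CRISPR (15), chaperones (7), cell division and vesicles (0), toxin-antitoxin (1) and transposases and integrases (10). The rule for named genes was the longest and shortest member of each RNA class, members with extra notes, every RNA gene outside rRNA and tRNA, and up to 4 members of each list in genome order with a gene name or a specific product. Where further genes are named, it was for a known function in motility, adhesion or RNA processing, for list matches whose function differs from the list's name, or after their values were seen. The alternatives were overlap of at least 50% of the RNA gene, gene features as reference, placements that keep the strand, coding sequences without pseudogenes, placements outside coding genes, members of at least 50 nt, identical locations counted once, and coverage by strand. Windows of 30 and 100 nt and the RefSeq table were added after the data were examined.

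Additional searches were chosen after the data were examined. TATA-like hexamers (TTTAWA, where W is A or T) were sought 38 to 22 nt upstream of start codons and compared with 1000 shuffles of the same windows and by Fisher's exact test between genes with a divergent neighbour and genes starting within 20 nt of a gene on the same strand. C/D box-like arrangements had the motifs RTGATGA, CTGA, TGATGA and CTGA with spacers of 8 to 20 nt. GC-rich stretches were merged 50-nt windows of at least 60% GC outside coding and RNA genes. The last pair was compared with 1000 shuffles that keep dinucleotide counts. The longest span without a tRNA gene was compared with 10000 random sets of positions, and lists of at least 10 members with 10000 circular shifts of their positions.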

Results

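Transcripts of Sulfolobus acidocaldarius, a thermoacidophilic archaeon of hot acidic springs, were sequenced in 3 libraries. The strain was MW001, a uracil auxotroph derived from the type strain DSM 639. One library came from planktonic cells of a liquid culture, 1 from biofilm cells adhered to a surface, and 1 from small RNA treated with RNase R, an exonuclease that degrades linear RNA from its 3′ end. The design asks which transcripts differ between the biofilm and the planktonic state, and which small RNA withstands RNase R. Each group had 1 library and no replicate, so no difference between growth modes could be tested against a spread between samples. The data analysed here are the annotated chromosome of DSM 639 that accompanies the libraries, which holds no value of any library. Read depth, the comparison of biofilm with planktonic cells and the RNase R library were therefore not analysed here. The sections that follow describe the RNA genes and the gene groups that those comparisons concern, with positions on that chromosome, and the sequence features that affect how reads from them can be assigned. No direction of change between growth modes is given for any gene.

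The stable RNA genes of the chromosome were few and, in this annotation, almost all placed between coding genes. The annotation held 52 RNA genes, made up of 48 tRNA genes, 3 rRNA genes and 1 other non-coding RNA, and 2245 coding sequences. The 23S rRNA gene Saci_1299 (positions 1103957 to 1106920, minus strand, 2964 nt) lay beside the 16S rRNA gene Saci_1300 (1107133 to 1108635, minus strand, 1503 nt). The 5S rRNA gene Saci_1516 (1293916 to 1294034, plus strand, 119 nt) lay elsewhere on the chromosome. The other non-coding RNA was that of RNase P, the ribonuclease that trims the 5′ end of tRNA precursors (SACI_RS11505, 585938 to 586244, plus strand, 307 nt). Of the 52 RNA genes, 50 (96.2%) lay between coding sequences, where 10000 random placements of the same lengths gave a mean of 8.54% and a 95% range of 1.92% to 17.3%. None of the RNA genes lay in sense within a coding sequence, where random placement gave 47.3%. The other 2 (3.85%, against 47.4% by chance) touched a coding gene on the opposite strand. These were the RNase P RNA gene, which overlapped Saci_0730 by 10 nt, and the tRNA-Thr gene Saci_1392, which overlapped Saci_1391 by 1 nt. All of these departures had an adjusted p of 0.0002 (two-sided permutation test, Benjamini-Hochberg), the smallest that 10000 placements can give. Annotation pipelines avoid calling coding sequences over tRNA and rRNA genes, so this outcome was largely fixed by how the annotation was made and describes the annotation alone.

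The tRNA genes covered 20 amino acid isotypes with 44 distinct anticodons. They were 69 to 91 nt long without their annotated introns, with a median of 75 nt, and 20 lay on the plus and 28 on the minus strand. The longest were the tRNA-Glu genes Saci_0470 (395126 to 395216) and Saci_0868 (694093 to 694183), at 91 nt each. Neither had an annotated intron, so any intron that was not called would be counted in that length. The shortest were tRNA-Asp Saci_0519 (427588 to 427656) and tRNA-Val Saci_0629 (500057 to 500125), at 69 nt each. An intron was annotated in 19 of the 48 genes (39.6%), and in all 19 it began 1 nt after the anticodon. These are the introns that the tRNA search called, and any that it did not call are missing here. The shared position may therefore follow from the search, which was not tested. The introns were 20.8 ± 10.4 nt long (SD, n = 19 introns), with a median of 18 nt. The longest, of 60 nt, lay in the tRNA-Trp gene Saci_0066 (49197 to 49256), and the shortest, of 13 nt, in the tRNA-Asn gene Saci_2335 (2181254 to 2181266). Excised tRNA introns are relevant to the RNase R library because archaeal introns can be ligated into circles, which have no 3′ end. None of the 19 introns held a box C motif (RTGATGA), and 2 held a box D motif (CTGA), those of the tRNA-Arg genes Saci_0170 and Saci_1453.

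The rRNA and tRNA genes were far richer in G and C than the chromosome, whose GC content was 36.7%. The 3 rRNA genes averaged 62.6% ± 2.16 (SD), with 60.4% for 23S, 62.8% for 16S and 64.7% for 5S. Random placement of 3 features of these lengths gave means of 32.1% to 41.3% (95% range, permutation test, adjusted p = 0.0003). The 48 tRNA genes averaged 68.2% ± 3.57, against 34.8% to 38.6% by random placement (adjusted p = 0.0003, permutation test). Both adjusted values derive from an unadjusted p of 0.0002, the smallest that the placements can give. Single tRNA genes ranged from 53.6%, in Saci_0629, to 75.0%. The RNase P RNA gene had 47.6%, above the range of 27.7% to 45.3% for random placement (permutation test, 1 gene, adjusted p = 0.0232). Against placements outside coding genes only, the same 47.6% did not pass (permutation test, 1 gene, p = 0.127). Those placements avoided coding sequences but not RNA genes, so they could fall on the GC-rich rRNA genes. That outcome therefore does not decide whether the gene is richer in GC than other sequence between genes.

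**Figure D1:**
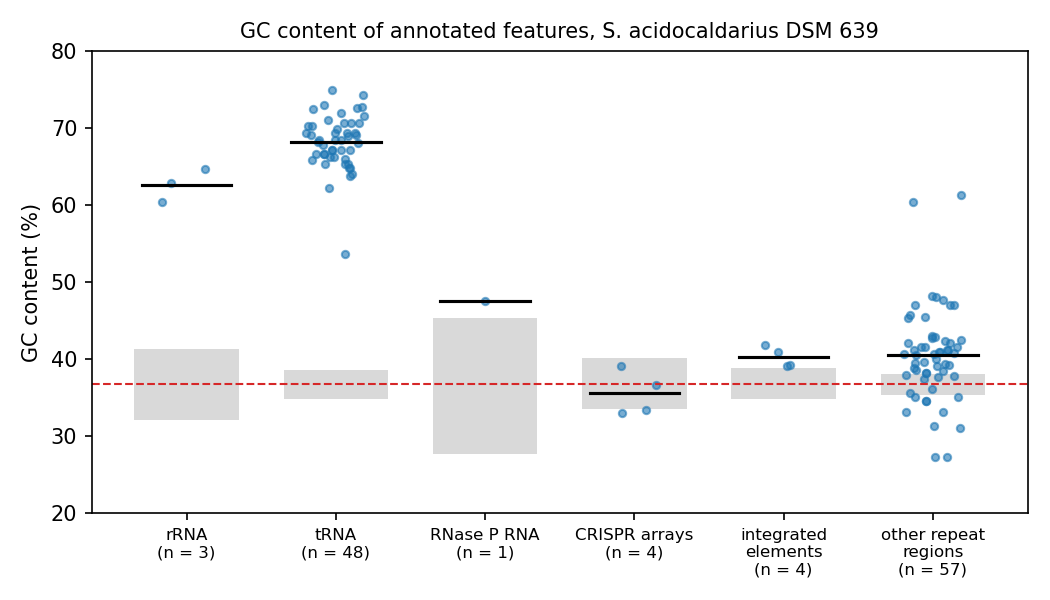
GC content (%, vertical axis) of each annotated feature by class (horizontal axis, n = number of features). Points are single features spread sideways for legibility, black lines are class means, grey bands are the 95% range of class means over 10000 random placements, and the red dashed line is the chromosome at 36.7%. The rRNA and tRNA points all lie above their grey bands.

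Coding sequences were compact and often overlapped. The 2245 coding sequences had a median length of 756 nt, lay in similar numbers on the plus (1110) and minus (1135) strands, and included 21 pseudogenes. A product of hypothetical protein was given for 815 of them (36.3%). Coding and RNA genes together covered 87.2% of the chromosome and left 285655 bp uncovered. Under 200 nt, the size of the small RNA fraction, there were 44 coding sequences besides the tRNA genes and the 5S rRNA gene, of which 24 were hypothetical. These are coding lengths, and the transcripts that carry them may be longer, so their presence in that fraction is not shown. Some overlapped a neighbour on the same strand, as Saci_0729 did by 14 nt. The 20 named ones included the ribosomal proteins L39 (Saci_1467, 156 nt), S30e (Saci_1348, 165 nt), L40 (Saci_0766, 171 nt), L37 (Saci_0642, 186 nt) and L24 (Saci_0697, 189 nt), and the protein translocase subunits SecG (Saci_0729) and SecE (Saci_1461), at 180 nt each. The shortest coding sequence was the hypothetical SACI_RS09540 (1787219 to 1787317), at 99 nt. These small coding sequences were named after their lengths were seen. On opposite strands, 301 coding sequences overlapped another coding sequence, in 151 pairs, with a median overlap of 14 nt. The longest such overlap was 80 nt, between Saci_0023 (quinolinate synthetase) and Saci_0024 (cysteine desulfurase), a pair chosen after its value was seen. On the same strand, 815 coding sequences overlapped in 476 pairs, with a median of 8 nt. Without strand information, reads that lie wholly within the opposite-strand overlaps cannot be assigned to 1 gene. Strand information would separate those reads, but not reads from within the same-strand overlaps. Stretches of 50 nt or more that also occur elsewhere on the chromosome were found in 39 coding sequences (1.74%). The count includes stretches repeated within the same gene, as in Saci_0054 (41179 to 41319 and 41362 to 41502). It is thus an upper bound on the genes whose reads could be ambiguous at this window length.

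The genes of the archaellum, the rotating filament used for swimming, lay for the most part in 1 cluster between a pair of paralogs that share a stretch of identical sequence. The list held 12 coding genes, of which 11 lay next to another member on the same strand and 4 were hypothetical. On the minus strand lay FlaJ (Saci_1172, 987941 to 989377), FlaI (Saci_1173, 989361 to 990902), FlaH (Saci_1174, 990906 to 991607) and flagellar protein F (Saci_1175, 991589 to 992083), of which FlaJ is the membrane platform and FlaI the motor ATPase. The filament protein itself, annotated flagellin, was Saci_1178 (993370 to 994284), named here in addition to the first 4. The cluster was flanked by Saci_1171 (987096 to 987896) and Saci_1180 (994943 to 995752), both on the plus strand and known as membrane-bound activators of the flagellin gene. They shared 69.1% of 789 aligned nt, and 181 nt of each (987125 to 987305 and 994972 to 995152) were identical. As a result 17.6% and 17.3% of their 50-nt windows occurred elsewhere, and reads from those windows cannot be told apart between these paralogs. They were the 2 members of the list with such windows. The list also held Saci_1210 (1029065 to 1029685) and Saci_1211 (1029690 to 1030832), known as repressors of archaellum synthesis.

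The loci of adhesive pili, which attach cells to surfaces and to each other, lay in 2 clusters and were poorly named in the annotation. The list held 10 coding genes, 7 of them hypothetical and none found by its product wording, since all came from locus tags fixed beforehand. The cluster known for UV-inducible pili ran from Saci_1493 (starting at 1270248) to Saci_1497 (ending at 1276756), and included the assembly ATPase Saci_1494 (1272319 to 1273728, annotated VirB) and a gene annotated endonuclease III (Saci_1497). The cluster known for adhesive pili ran from Saci_2314 (starting at 2159485) to Saci_2319 (ending at 2166295) and included the assembly ATPase Saci_2317 (2161884 to 2163566). A tRNA-Gly gene, Saci_2315 (2160071 to 2160161), lay within it. None of the 10 coding genes held a 50-nt window found elsewhere. The list of biofilm regulators held 3 genes, all on the plus strand. They were Saci_0446 (380078 to 380428), a known regulator of biofilm formation and motility, Saci_1223 (1041456 to 1041827) and Saci_1242 (1057460 to 1057792). Of these, Saci_0446 overlapped a coding gene on the opposite strand by 30 nt and Saci_1223 by 4 nt.

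The list for the S-layer, the protein coat of the cell, and its glycosylation held 17 genes. The S-layer proteins Saci_2354 (2198399 to 2199826) and Saci_2355 (2199897 to 2204171) were annotated as hypothetical. The other 15 were glycosyl transferases, among them Saci_0201, Saci_0275, Saci_0294 and Saci_0807. They were taken in by product wording alone, so a role of theirs in S-layer glycosylation is not shown. The list of respiratory terminal oxidases held 15 genes, 10 of them next to another member on the same strand. It included the cytochrome c oxidase polypeptide Saci_0097 (72941 to 74701) and the sulfocyanin Saci_1747 (1507564 to 1508253). By wording it also took in the succinate dehydrogenase genes Saci_0981 and Saci_0982 and a cytochrome P450 (Saci_2081), which are not terminal oxidases.

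Genes of translation made up the longest list, with 80 members, of which 56 lay on the minus and 24 on the plus strand. Of these, 47 lay next to another member on the same strand, 34 overlapped a coding gene on the same strand and 5 were under 200 nt. The first in genome order were ribosomal proteins S13 (Saci_0080, 62537 to 63049), S4 (Saci_0081, 63067 to 63597), S11 (Saci_0082, 63581 to 63979) and L18e (Saci_0084, 64785 to 65141), and S4 and S11 shared 17 nt. By wording the list also took in the transcription factors NusA (Saci_0689 and Saci_0767) and Spt5 (Saci_1460). The list of RNA-guided RNA modification held 6 genes. It included fibrillarin (Saci_1346, 1147005 to 1147700), the methylase of C/D box guide complexes, and Gar1 (Saci_1340, 1142977 to 1143249), a subunit of H/ACA guide complexes. Cbf5, the pseudouridine synthase of those complexes, was annotated in 2 parts (Saci_0811, 649445 to 650152, and SACI_RS03885, 650217 to 650471). The list of RNA degradation held 9 genes, 8 of them on the minus strand. It included the exosome genes Saci_0609 (487042 to 487872) and Saci_0610 (487876 to 488607, Rrp41), which belong to the complex that degrades RNA from the 3′ end. Saci_0610 overlapped the RNA-binding protein gene Saci_0611 by 35 nt on the same strand. By wording the list also took in exodeoxyribonuclease III (Saci_0129), which acts on DNA.

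The chaperone list held 7 genes, among them 3 thermosome subunits (Saci_0666, Saci_1203 and Saci_1401), the prefoldin subunit Saci_0605 and the heat-shock protein Saci_0922. No thermosome gene held a 50-nt window found elsewhere. The toxin-antitoxin list held 1 gene, the antitoxin Saci_0468 (394465 to 394713). It was matched by product wording, so genes of this kind under other names may be missing. The PIN domain-containing protein gene Saci_0467 (394110 to 394478), which overlaps Saci_0468 by 14 nt on the same strand, was not matched. The list of cell division and vesicle genes, sought by the names Cdv, ESCRT, Vps4, SegA and SegB, matched 0 products. That 0 comes from the product wording and does not show that such genes are absent. The 5 products that hold the words cell division carry none of these names and were not part of the list. Among them are Saci_1373 and Saci_1374, and also the cell division control proteins Cdc6 Saci_0001 and Saci_0722. Whether any of the 5 is a Cdv gene under another name was not examined. The list of transposases and integrases held 10 genes, with a mean GC content of 44.2% ± 6.12 (SD, n = 10 genes), and its first members were the transposases Saci_0269, Saci_0487, Saci_0503 and Saci_0504.

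CRISPR arrays, whose transcripts are cut into small guide RNAs against viruses and plasmids, were annotated at 4 places and held 226 repeats and 222 spacers. Spacers averaged 36.0 ± 1.72 nt (SD, n = 222). The first array (1650669 to 1658594) held 132 spacers of 35.9 ± 1.64 nt and the second (1670962 to 1675586) 77 spacers of 35.8 ± 1.55 nt. The 24-nt repeat of the first, GTTTTAGTTTCTTGTCGTTATTAC, was the exact reverse complement of that of the second, GTAATAACGACAAGAAACTAAAAC. The third array (1786307 to 1786584) held 3 spacers of 38 ± 2.65 nt and the fourth (1825971 to 1826628) held 10 of 38.3 ± 2.00 nt, both with repeats of 25 nt. The second array lay 222 nt from the Cas1 gene Saci_1881 and the fourth 356 nt from the Cas1 gene Saci_2011, while the third lay 35138 nt from the nearest CRISPR-associated gene, Saci_2008 (Cas6). Of the spacers, 217 were distinct, and none had an exact match on the chromosome outside the arrays. The CRISPR list held 15 coding genes with a mean GC content of 41.8% ± 3.47, of which 11 lay next to another member on the same strand. The first in genome order were Saci_0274 (Cas4), Saci_0449, Saci_1873 and Saci_1874 (Cas7/Csc2). The arrays themselves averaged 35.6% ± 2.85 GC (n = 4 arrays), within the range of random placement (permutation test, p = 0.484).

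The annotation also marked 4 integrated elements, each with at least 1 tRNA gene on the direct repeats at its ends. SA3 (395168 to 427655, 32488 nt, 42 coding genes) overlapped tRNA-Glu Saci_0470 at its left end and tRNA-Asp Saci_0519 at its right end. SA4 (500054 to 507566, 8 coding genes) held the tRNA-Val gene Saci_0629 at its left end and overlapped the tRNA-Val gene Saci_0638 at its right end. SA1 (1231708 to 1240441, 7 coding genes) had tRNA-Gln Saci_1451 and SA2 (1300373 to 1306069, 7 coding genes) had tRNA-Arg Saci_1522. Their GC content averaged 40.3% ± 1.35 (n = 4 elements), above the 34.8% to 38.9% of random placement (permutation test, adjusted p = 0.0123). A further 57 repeat regions of 102 to 487 nt, 46 of which touched coding genes, averaged 40.5% ± 6.13 (permutation test, adjusted p = 0.0006, from an unadjusted p of 0.0002, the smallest possible). Several of these regions are copies of each other with the same GC content, such as 41179 to 41319 and 41362 to 41502 (41.1% each). The test drew each copy independently, so its random range is too narrow and its p too small. Some regions also lie in integrated elements or hold a tRNA gene. The tests on arrays, elements and repeat regions were chosen after the data were examined.

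**Figure D2:**
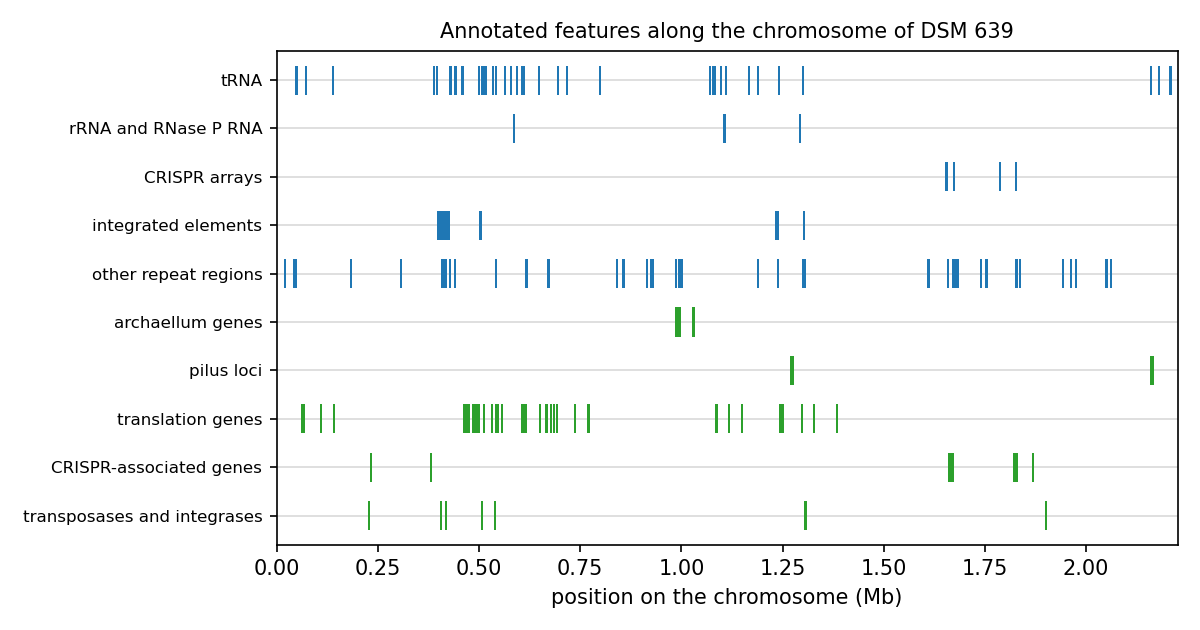
Positions of annotated features along the chromosome (horizontal axis, Mb); each row is a feature class, blue for RNA genes, arrays, elements and repeats and green for coding gene lists. Features shorter than 5 kb are drawn 5 kb wide so that each is visible. The archaellum list sits in 2 places and the pilus list in 2, and the 4 CRISPR arrays all lie at or beyond 1650669.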

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

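The alternatives named without a mark were fixed before the data were examined. Those using the RefSeq table, leaving out pseudogenes for placement, changing the window length or changing the sequence searches were chosen afterwards. Of 35 recomputed values, 29 kept their direction and their side of the threshold or, for counts without a test, stayed within 1.5 times the main count, but 9 of these could not have moved, which leaves 20. RNA gene placement, largely fixed by the annotation itself, kept all calls in every setting run, with 0% antisense and 100% between coding genes when an overlap of at least 50% was required. Gene features as reference have the bounds of the coding sequences, the minimum of 50 nt removed no RNA gene, no features shared a location, and shorter spacers could only keep the 0 of the C/D box search, so these settings are the 9 and show no stability. Leaving 21 pseudogenes out of 2245 coding sequences could not pass the limit of 1.5 times either. The 20 are therefore not all free to move. The GC content of the RNase P RNA gene, 47.6%, was no longer past the threshold against placements outside coding genes (permutation p = 0.127). Such placements could fall on the GC-rich rRNA genes, so this loss decides nothing about the gene, and its cause was not tested. Coverage was 42.7% on the plus strand alone and 44.6% on the minus strand alone, by construction of the setting. Coding genes with shared windows numbered 60 at 30 nt and 22 at 100 nt, also by construction. The looser spacer in the C/D box search gave 1 arrangement in place of 0. Other scalings of the libraries, the filter on low counts and other pseudocounts for biofilm against planktonic cells were not run, as no library values were analysed. No paired analysis was possible because each group has 1 library and no value of it was analysed.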

Other observations

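All tests in this part were chosen after the data were examined. The tRNA genes left a long part of the chromosome free. Between tRNA-Arg Saci_1522 and tRNA-Gly Saci_2315 (1300418 to 2160070) no tRNA gene was annotated over 859653 nt, 38.6% of the chromosome, and the next longest gap was 271700 nt. With 48 random positions the longest gap had a median of 197705 nt and never exceeded 731035 nt (one-sided permutation p = 0.0001, the smallest possible). Treating tRNA genes within 10 kb as 1 of 26 clusters gave p = 0.0003 (one-sided permutation). The same span held 35.1% of all coding genes and 2 of the 80 translation genes (2.5%). Circular shifts, which keep clusters of genes together, did not separate that count from chance (permutation p = 0.115, adjusted p = 0.918 over 8 lists). By contrast 13 of the 15 CRISPR genes and 12 of the 15 genes of the terminal oxidase list lay in the span, again not past the test (p = 0.582 and p = 0.364, circular-shift permutation). The 13 CRISPR genes lie between 1661804 and 1868964, so each shift moves them almost as 1 block. With a span of 38.6% of the chromosome, such a block falls inside it in many shifts. The test could hardly pass for lists in few clusters and decides nothing about them.

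The RefSeq gene table of the same chromosome differed from the annotation analysed here in a few RNA genes. Saci_0095, in the series' annotation a hypothetical pseudogene (72226 to 72464, 239 nt), is listed there as the RNA of the signal recognition particle (ffs, 72170 to 72476, 307 nt), which takes nascent membrane proteins to the translocase. Both tRNA genes of 69 nt, Saci_0519 and Saci_0629, are not in that table, and both lie on direct repeats of integrated elements. The 23S rRNA gene is 3039 nt there, against 2964 nt, and the 16S rRNA gene 1494 nt, against 1503 nt. Of 2246 shared locus tags, 2004 had the same start and end, and 10 changed their type, among them the citrate synthase gene gltA (Saci_0243), a pseudogene there, and cas4 (Saci_2012), a pseudogene in the series' annotation. A count of reads per gene from the annotation analysed here would assign reads of the signal recognition particle RNA to no RNA gene.

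GC-rich stretches lay outside the annotated genes more often than base composition gives. Outside coding and RNA genes there were 21 stretches with a 50-nt window of at least 60% GC, while 1000 dinucleotide shuffles gave a mean of 7.83 and at most 16 (one-sided permutation p = 0.001, the smallest possible), which argues against base composition as the whole cause; the count was 55 against 32.7 with windows of at least 55 percent GC and 8 against 1.25 with 70-nt windows, each with the same p. Annotated repeats and integrated elements held 8 of the 21 (38.1%), which argues against annotated mobile sequence as the whole cause. Without them 247035 of the 285655 uncovered bp were searched. There 13 stretches remained, against a shuffle mean of 5.41 and at most 13 (one-sided permutation p = 0.002). Stretches were thus denser in the annotated repeats and elements than in the remaining sequence. Mobile sequence without annotation was not tested. Of the 21, 4 overlapped a RefSeq gene, namely the signal recognition particle RNA, the longer 23S rRNA and 2 protein-coding genes. Of the other 17, 2 lay beside the rRNA genes and some lay in integrated elements. With repeats, elements, RefSeq genes and regions beside rRNA genes taken out of both the sequence and its shuffles, 9 stretches remained against a mean of 4.04 and at most 10 (one-sided permutation p = 0.005). Structural RNA genes with no RNA annotation may account for some. The region listed as signal recognition particle RNA had 59.0% GC, above the 45.3% that bounds random windows (permutation p = 0.0038). That test rests on 1 region, which overlaps 1 of the 21 stretches chosen for high GC, so its value partly restates the choice. The region is not among the 9, which have no test of transcription here. Saci_0095, which lies in that region, had the highest GC content of the 2245 coding sequences (57.7%).

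TATA-like hexamers were placed close to start codons. TTTAWA lay in the window 38 to 22 nt upstream of 179 of 829 genes with a divergent neighbour (21.6%, 95% Wilson interval 18.9% to 24.5%), against a mean of 8.05% in 1000 shuffles of the same windows (one-sided permutation p = 0.001, the smallest possible), which argues against base composition as the whole cause. Genes starting within 20 nt of a gene on the same strand had it in 38 of 724 cases (5.25%, 3.85% to 7.12%), an odds ratio of 4.97 between the groups (Fisher's exact test, p = 9.59e-22). By that definition the close windows lie in the upstream gene, so the contrast may also reflect sequence inside genes against sequence between genes. The close windows were richer in GC (32.6% against 22.4%). Each set also exceeded its own shuffles, by 2.68 times for divergent and 1.84 times for close genes. The odds ratio therefore does not measure promoters alone. The other 671 genes, in neither group, had the hexamer in 154 cases (23.0%, 19.9% to 26.3%). Matches peaked 30 nt upstream, at 3.98% of divergent genes, against 0.388% ± 0.209 (SD over positions) at 60 to 120 nt. A candidate explanation is that promoters close to the start codon are frequent, so that many transcripts have short leaders; it was tested on sequence alone, without transcript ends.

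C/D box guide RNAs, a class of small RNA that directs methylation of rRNA and tRNA, had no gene in the annotation analysed here. The strict search found 0 arrangements outside coding genes, 0 in coding genes and 0 in each of 1000 shuffles, so neither base composition nor C/D box sRNA genes that carry no annotation could be tested, since a search that finds nothing anywhere decides nothing. With a spacer between the inner boxes of 0 to 20 nt there was 1 arrangement outside coding genes and 0 inside them, and 0 of 1000 shuffles held any. That setting was 1 of 3 tried and the arrangement is a single one, so no p is given for it. The arrangement lay between Saci_1317 and Saci_1319 (1122974 to 1123020, plus strand, 47 nt) and read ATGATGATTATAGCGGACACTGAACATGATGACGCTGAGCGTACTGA. Whether it is transcribed was not tested.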
